A study of Mus musculus with 12 samples.

How the data were processed

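RNA was measured in 12 libraries of mouse splenic B cells, 2 for each of 6 sorted groups, from 2 hosts numbered 196 and 197 per the labels. Per the labels' protocols, B cells labelled with a division dye were transferred into B-cell-lacking hosts that were given LPS, and cells were sorted on day 3 by dye content and CD138. Per the labels' protocols, RNA came from 40000 sorted cells with ERCC spike-in RNA added before extraction, libraries were made with a stranded mRNA kit and 11 PCR cycles, and reads were 50 bp paired-end on a HiSeq2500. Per the submitters' processing notes, Picard and R 3.2.2 were used with the mm9 genome, and the aligner and the counting program are not given in the sources used here. The design text also speaks of bisulfite libraries, which were not analysed here.

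The deposited table held 21761 genes, of which 90 had no symbol (0.05 to 0.094% of counts) and 5325 had 0 counts in every library. The deposited counts are reads over the exons of UCSC mm9 KnownGenes per the file headers' readme. The deposited RPM values are counts over a library total (21.83 to 27.52 when divided by 1e6), of which 40.2 to 48.9% fell in neither genes nor spike-ins, as checked from the values. The deposited FPKM values equal RPM over exon length. The deposited mRNAs per cell are FPKM multiplied by 1 factor per library (0.1387 to 0.769), which equals the summed spike-in molecules per cell over the summed spike-in FPKM. The spike-in molecule numbers also served to relate spike-in FPKM to molecules and to split the spike-ins by abundance. All lengths and unit relations were checked in every library and held. The counts and the mRNAs per cell were analysed. The RPM and FPKM columns were not used further, apart from the spike-in FPKM set against molecules below.

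Libraries held 11551585 to 14975133 gene counts and 113723 to 683173 spike-in counts (0.473 to 2.71% of the library total). Between 43 and 57 spike-ins had 10 or more counts, and the top one held 43.4 to 47.3% of spike-in counts. Among those with 10 or more counts, log FPKM followed log molecules with r of 0.9748 to 0.9841 and slopes of 0.896 to 0.957. Within groups the 2 libraries had a chi-square over degrees of freedom of 2.48 to 4.38 and r of 0.99257 to 0.99458 on log2 CPM. Where a group had 0 counts, a floor of 3 counts over its 2 libraries gives the bound "at least". Where a group had 1 to 3 counts, the ratio is given with a 95% interval of counting error. Such intervals leave out the spread between hosts, and copies made by PCR were not removed by molecular tags.

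Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM factors (0.9456 to 1.021), filterByExpr at its defaults with the 6 groups (12049 genes kept, 9712 not tested), glmQLFit over all 12 libraries with group means only, and glmQLFTest for each of 7 comparisons. The slope per division was fitted in the 10 libraries outside Div8pos (11836 genes), with 8 or more divisions entered as 8. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. "Higher" and "lower", or "rose" and "fell", are used of called genes. Group levels are mean CPM ± SD over n = 2, with TMM factors for genes and without them for summed lists. Per-cell tests used limma 3.58.1 with trend on log2 of mRNAs per cell plus 0.1. Other statements of "per cell" for genes and lists come from edgeR with library sizes scaled to the summed spike-in counts. The total of mRNAs per cell was related to the division number by Pearson and Spearman correlation, with a permutation test that shuffled divisions within hosts 100000 times (smallest p 1.0e-05) and, within 1 host, by all orders. With 2 against 2 libraries an exact test cannot go below p = 0.333, so ratios between groups are given as values with SD over hosts.

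Gene lists were written before the data were examined: 24 in all, for B cell identity, plasma cell, MHC class II, unfolded protein response and ER secretion, mitosis, DNA replication, MYC and ribosome biogenesis, oxidative phosphorylation, glycolysis, interferon, NF-kB and TLR response, class switching and somatic mutation, DNA methylation and chromatin regulators, apoptosis, quiescence and recirculation, marginal zone and B1 cells, immunoglobulin constant and joining genes, and 7 other cell types. Lists with 5 or more tested members (22) were tested with camera at its preset correlation of 0.01, adjusted over lists within a comparison, and again with an estimated correlation. List medians and means are of log2 fold changes. The named-gene rule, also written before the data were examined, took the genes Sdc1, Prdm1, Irf4, Xbp1, Pax5, Bach2, Myc, Dnmt1, Dnmt3a and Uhrf1 among its anchors. It added, for Div1 against Div0, Div8neg against Div0 and Div8pos against Div8neg, the 10 called genes with the largest fold change in each direction that had at least 10 CPM in the higher group and the same sign in both hosts. It took the first 4 in each direction for the other comparisons and the trend, and up to 4 called members of each list described. Some genes that the rule takes are not reported here. Ribosomal proteins and the other families in the closing section were chosen after values were seen.

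The tests were tried on simulated counts made from each gene's mean level and from the spread fitted to genes of like level. In them 50 genes changed at each of 4 fold sizes (1.25, 1.5, 2 and 4) and all others were unchanged. The late comparisons here differ from that, as most genes were called in them. Totals per cell were held equal, so the simulated data hold no change in total mRNA and no spike-in noise. For Div1 against Div0 edgeR found 52, 94, 98 and 98% with 12 false calls among 11832 genes, for Div8neg against Div0 52, 94, 96 and 100% (9 of 11798), for Div8pos against Div8neg 48, 78, 94 and 100% (9 of 11803) and for the slope 60, 92, 96 and 100% (8 of 11748). On the same simulated data limma per cell gave 50, 94, 98 and 98% (14 false calls), 52, 92, 98 and 100% (11) and 44, 80, 94 and 100% (4), and DESeq2 gave 40, 92, 96 and 94% (4), 36, 84, 94 and 100% (1) and 38, 70, 86 and 100% (5). With 1 of 22 lists raised, camera called that list and 0 others. As genes were drawn independently, this does not show how often camera calls lists whose genes vary together.

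Libraries of 1 number come from 1 host, so the hosts pair the libraries across groups. Deviations from the group means correlated within hosts at 0.0204 to 0.299 over 15 pairs of groups, 9 of them over 0.1. Alternatives were DESeq2 1.42.0 size factors, spike-in scaling, the DESeq2 Wald test, no filter, a stricter filter (1 CPM and a mean of 10 counts), a minimum log2 fold of 1 (0.125 per division), the host as a block, each library left out, and the 2 groups alone. For the slope, the Div8pos libraries were added. For the totals, gene counts over spike-in counts, leaving out the 20 highest genes, and each host alone were tried. For the per-cell tests a pseudocount of 1 or 0.01, no filter, a mean of at least 1 mRNA and the block were tried. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 served for totals and figures. Read-level files were not used here.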

Results

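Messenger RNA was counted in mouse splenic B cells that had divided 0 to 8 or more times in the 3 days after lipopolysaccharide (LPS). The B cells carried a division dye and had been transferred into hosts that lack B cells. Cells were sorted at 0 (Div0), 1 (Div1), 3 (Div3) and 5 (Div5) divisions. Cells at 8 or more divisions were split by the plasma cell surface protein CD138 into negative (Div8neg) and positive (Div8pos) cells. Each group held 2 libraries, 1 from each of 2 hosts (196 and 197), so n = 2 per group. The p-values of gene tests rest on the spread between the 2 libraries of a group, shared over the groups. The p-values for total mRNA rest on the order of the groups within hosts. None of them speaks for more than these 2 hosts. The 12 libraries held 11551585 to 14975133 counts over genes and 113723 to 683173 counts over ERCC spike-in RNAs, and 10964 to 11498 genes had 10 or more counts in a library. As spike-ins were added to a fixed number of cells, values per cell could be had as well. A change is relative to all genes unless it is said to be per cell. The camera test compares a list with all other genes under either scaling. A camera p-value given per cell is from spike-in scaling and does not test whether the list changed per cell.

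The first question was how much messenger RNA each cell held. Totals count only the genes of the deposited table, in which none of the antibody constant genes looked for was found by symbol. The total was 30490 ± 4360 mRNAs per cell in Div0 (mean ± SD, n = 2), 51390 ± 12100 in Div1 and 48560 ± 7030 in Div3. It reached 71520 ± 4990 in Div5, 100300 ± 4760 in Div8neg and 163000 ± 15600 in Div8pos. The ratio of Div1 to Div0 was 1.67 ± 0.158 over the 2 hosts, that of Div8neg to Div0 was 3.31 ± 0.318, and that of Div8pos to Div8neg was 1.63 ± 0.233. Across the 12 libraries the total rose with the number of divisions (r = 0.865, permutation p = 1.1e-04; rho = 0.947, permutation p = 8.0e-05). These p-values were not adjusted for the use of both correlations or for the alternative forms of the total. Without both Div0 libraries r was 0.825 (permutation p = 0.00511), and it was 0.909 without both Div8neg libraries and 0.943 without both Div8pos libraries. Within host 196 alone r was 0.865 and within host 197 alone 0.879 (n = 6, exact permutation p = 0.00833 in both). Scaled to the spike-ins, the median log2 change over all genes was 0.74 in Div1 against Div0, -0.08 in Div3 against Div1, 0.53 in Div5 against Div3 and 0.49 in Div8neg against Div5. The median so scaled was 1.68 in Div8neg against Div0, 0.60 in Div8pos against Div8neg, 2.23 in Div8pos against Div0, and 0.18 per division along the trend. Tested per cell with limma, 9286 genes differed between Div1 and Div0 (9270 higher, 16 lower), 10846 between Div8neg and Div0 (10645 higher, 201 lower) and 8233 between Div8pos and Div8neg (6270 higher, 1963 lower). The Div1 count was 840 without the Div0 library of host 196 and 848 without the Div1 library of host 197.

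**Figure D1:**
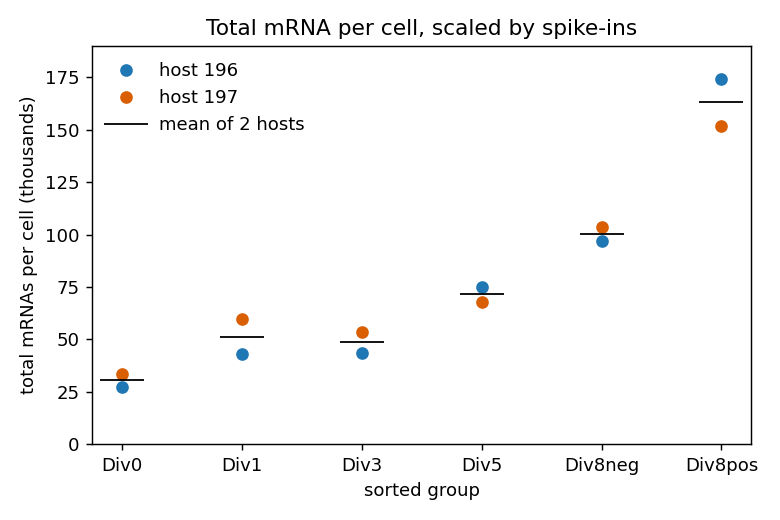
Total mRNAs per cell in each library by group and host, with the group mean as a dash. The mean was 30490 in Div0 and 163000 in Div8pos.

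The second question was what changed at the first division, from Div0 to Div1. Flt3, which encodes the receptor for FLT3 ligand, rose from 88.57 ± 6.47 to 277.3 ± 4.02 CPM (counts per 1e6 counts; 3.13-fold, log2 1.65, SE 0.10, adjusted p = 2.22e-07). Pde2a, which encodes a cyclic nucleotide phosphodiesterase, fell from 28.83 ± 0.892 to 3.90 ± 0.108 CPM (7.39-fold lower, log2 -2.89, SE 0.23, adjusted p = 1.95e-06). The gene for the de novo DNA methyltransferase, Dnmt3a, rose 1.45-fold from 142.5 ± 9.80 to 206.2 ± 7.91 CPM (adjusted p = 0.000115). Fas, which encodes a death receptor, rose from 13.57 to 32.69 ± 0.852 CPM (2.41-fold, adjusted p = 6.83e-06). Shank1, whose product is a scaffold protein best known at synapses, rose from 78.68 ± 3.83 to 192.9 ± 13.4 CPM (2.45-fold, adjusted p = 2.18e-07). The other large rises were in Myb (2.49-fold, a transcription factor of blood progenitors), Aire (2.48-fold, the autoimmune regulator), Fam64a (2.47-fold), Psrc1 (2.46-fold, a spindle protein), Rec8 (2.39-fold, a meiotic cohesin), Depdc1a (2.38-fold) and Dll1 (2.31-fold, a Notch ligand). The large falls took in Hspa1b (4.01-fold lower, a heat shock protein whose reads can also come from its near copy Hspa1a), Mapk12 (3.89-fold lower, a p38 kinase) and Cacna1i, which encodes a calcium channel subunit and fell from 95.02 ± 12 to 29.53 ± 8.16 CPM (3.26-fold lower). Hopx (2.34-fold), Dusp3 (2.27-fold), Nr1d2 (2.21-fold), Tha1 (2.18-fold), Cxcr4 (2.15-fold, the receptor for CXCL12) and Spns2 (2.08-fold, an exporter of sphingosine 1-phosphate) were lower relative to all genes, but per cell none of these 6 passed (adjusted p = 0.0759, 0.0824, 0.131, 0.201, 0.130 and 0.260). Xbp1, a transcription factor of secretory cells, was at 118.6 CPM in Div0 and 96.88 in Div1 and passed with the host as a block but not without it (adjusted p = 0.00617 and 0.0752). Irf4 (1.22-fold lower, adjusted p = 0.0106) and Bach2 (1.18-fold lower; 0.0246) flipped per cell to log2 values of 0.47 and 0.50. Irf4 did not pass without Div0 of host 196 (0.0695) or Div1 of host 196 (0.0821), nor Bach2 without Div0 of host 196 (0.210) or Div1 of host 197 (0.208), by DESeq2 (0.0891) or in a fit of the 2 groups alone (0.0526). Uhrf1, the partner of the maintenance methyltransferase, was 1.31-fold higher (adjusted p = 0.0173; 0.117 without Div0 of host 196 and 0.205 without Div1 of host 197). The genes Sdc1 (adjusted p = 0.197), Prdm1 (0.688), Pax5 (0.946), Myc (0.940) and Dnmt1 (0.242) did not pass, though per cell Pax5, Myc and Dnmt1 rose (adjusted p = 0.00271, 0.00236 and 0.000698).

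Mitosis genes made up the clearest group at the first division. Of 46 tested, 44 rose and 0 fell (45 rose when adjusted over the list alone), among them Anln (2.27-fold, a cytokinesis protein, to 34.34 ± 0.794 CPM), Cenpe (2.05-fold, a kinetochore motor, 52.12 to 106.4 ± 6.70), Cenpf (1.96-fold) and Cdc25c (1.91-fold). The camera test of the mitosis list gave an adjusted p of 3.7e-65 at its preset correlation, and adjusted p = 0.125 with an estimated correlation. Of 41 DNA replication genes, 11 rose and 1 fell (16 and 2 over the list alone), with Mcm10 at 1.45-fold, Tyms at 1.42-fold and Rrm2 at 1.41-fold (camera adjusted p = 5.8e-06, and adjusted p = 0.718 with an estimated correlation). The list of quiescence and recirculation genes had 2 higher and 5 lower of 26 (2 and 6 over the list alone, camera adjusted p = 0.0013, and adjusted p = 0.387 with an estimated correlation). In it Zfp36l2 was 1.6-fold lower (an RNA-binding regulator of messenger RNA decay) and S1pr1 1.43-fold lower (the receptor that guides exit from lymphoid tissue). Per cell that family flipped to a median of +0.56, with 19 genes higher and 0 lower. Zfp36l2 flipped to 0.06 and S1pr1 to 0.22 on the log2 scale (not passing, adjusted p = 0.804 and 0.343). With spike-in scaling the camera adjusted p of the list was 0.286. No gene of the MYC and ribosome biogenesis list of 41 passed, though with the host as a block 7 were lower and 0 higher. Its median of -0.13 was called by camera (adjusted p = 9.5e-06, and adjusted p = 0.718 with an estimated correlation). Per cell that median flipped to +0.62, with 40 of 41 genes higher and 0 lower (camera adjusted p = 0.720 with spike-in scaling). The DNA methylation and chromatin regulators had 5 higher and 2 lower of 27 (6 and 2 over the list alone), with Ezh2 at 1.40-fold and Hells at 1.32-fold. Camera called that list at adjusted p = 0.044 (adjusted p = 0.587 with an estimated correlation), but not without the Div0 library of host 196 (0.0695) or the Div1 library of host 197 (0.0809). The apoptosis list had 3 higher and 0 lower of 20, Bid among them at 1.35-fold (6 and 2 over the list alone, camera adjusted p = 0.037, and adjusted p = 0.387 with an estimated correlation; 0.0695 without Div0 of host 196, 0.0870 without Div1 of host 197 and 0.0612 without a filter on low counts). The plasma cell list had 1 higher and 5 lower of 26 (2 and 6 over the list alone, camera adjusted p = 0.037, and adjusted p = 0.632 with an estimated correlation; 0.0502 without Div1 of host 196 and 0.129 without Div0 of host 197). Per cell the median of the plasma cell list flipped from -0.13 to +0.61. Of 63 genes for the unfolded protein response and secretion from the endoplasmic reticulum (ER), 0 rose and 2 fell (0 over the list alone). Camera called that list lower at 0.037 (adjusted p = 0.877 with an estimated correlation), but not without Div0 of host 197 or Div1 of host 196. Per cell its median flipped to +0.69, with 59 of 63 genes higher and 0 lower (camera adjusted p = 0.631 with spike-in scaling). The interferon list (6 higher, 1 lower of 41, camera adjusted p = 0.130) did not pass, though Ifih1, which encodes an RNA sensor, rose 1.87-fold. Nor did the NF-kB and TLR list (7 and 1 of 39, camera adjusted p = 0.064), in which Bcl2a1b rose 1.46-fold, with reads that can also come from its paralogs. Calls were few in B cell identity (2 higher and 4 lower of 30, camera adjusted p = 0.620), MHC class II (0 of 12; 0.930) and glycolysis (0 and 2 of 21; 0.170). Oxidative phosphorylation (0 of 56; 0.540), class switching (0 of 16; 0.750) and marginal zone and B1 cells (1 and 1 of 13; 0.820) did not pass as lists either.

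By edgeR, 1129 of 12049 genes differed between Div1 and Div0 (659 higher, 470 lower), 119 of them by a log2 fold change of 1 or more (75 higher, 44 lower). Scaled to the spike-ins the split was 9822 higher and 16 lower, and with the host as a block the count was 1713 (944 higher, 769 lower). The count was 670 without Div0 of host 196, 643 without Div0 of host 197 and 624 without Div1 of host 197.

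**Figure D2:**
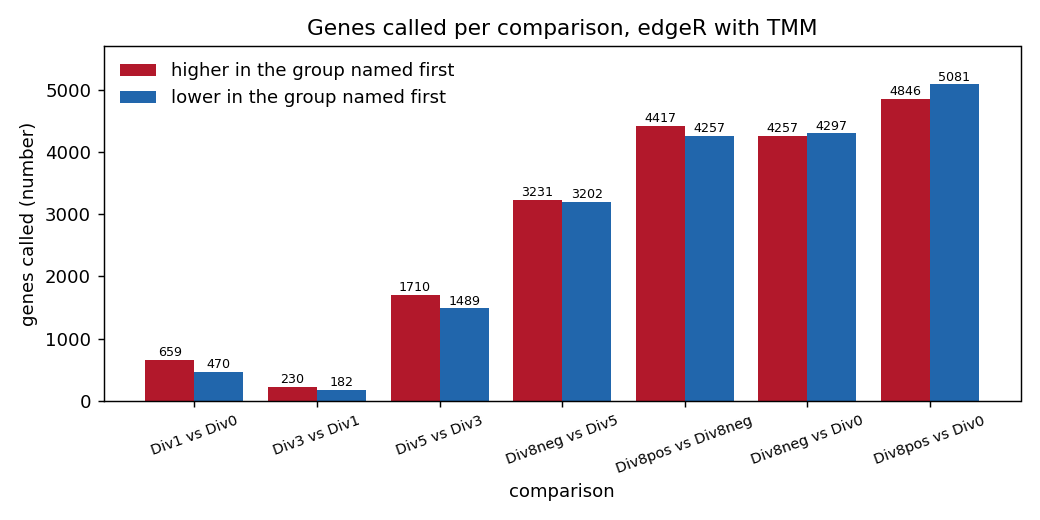
Genes higher and lower in each comparison (edgeR, false discovery rate 0.05, relative to all genes). The number called was 1129 at the first division and 8674 between Div8pos and Div8neg.

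The third question was what changed between 1 and 3 divisions. Cxcr3, which encodes a receptor for interferon-induced chemokines, rose from 21.24 ± 3.94 to 70.88 ± 5.29 CPM (3.31-fold, adjusted p = 3.27e-06). Cpd (3.40-fold, a carboxypeptidase), Trabd2b (3.32-fold, a protease that acts on Wnt proteins) and Gatm (3.30-fold, an enzyme of creatine synthesis) also rose. Cacna1i (2.79-fold), the cholesterol exporter gene Abca1 (2.51-fold), Cecr2 (2.27-fold) and Slc41a2 (2.26-fold) were lower. Itgb7, which encodes an integrin of gut homing, fell from 112.7 to 59.53 CPM (1.89-fold lower). The mitosis list had 2 higher and 0 lower of 46 (4 and 1 over the list alone, camera adjusted p = 4.1e-11, and adjusted p = 0.609 with an estimated correlation), with Cenpe at 1.34-fold, which did not pass per cell (adjusted p = 1). In the marginal zone and B1 list 3 of 13 rose and 0 fell (4 and 1 over the list alone, camera adjusted p = 0.0069, and adjusted p = 0.274 with an estimated correlation), among them Zbtb32 (2.69-fold, a transcriptional repressor) and S1pr3 (1.86-fold, a sphingosine 1-phosphate receptor). The plasma cell list had 0 higher and 4 lower of 26, the same over the list alone (camera adjusted p = 0.0056, and adjusted p = 0.584 with an estimated correlation; 0.0585 without Div3 of host 196). Oxidative phosphorylation had 0 of 56 called and a camera adjusted p of 0.00015 (adjusted p = 0.924 with an estimated correlation; 0.244 without Div3 of host 197), and its median of 0.07 turned to -0.02 per cell (0.130). Quiescence and recirculation genes had 0 of 26 called (1 and 5 over the list alone, camera adjusted p = 0.0039, and adjusted p = 0.584 with an estimated correlation; 0.0944 without Div3 of host 196 and 0.0558 without Div1 of host 197). B cell identity (2 and 3 of 30, camera adjusted p = 0.730) did not pass as a list, though Faim3, which encodes a receptor for IgM, was 1.37-fold lower (per cell adjusted p = 0.689). MHC class II (0 of 12) passed with the host as a block but not without it (camera adjusted p = 0.0225 and 0.073). By edgeR 412 genes differed (230 higher, 182 lower; 77 by a log2 fold change of 1 or more), against 755 with the block. The count was 138 without Div1 of host 196, 173 without Div3 of host 197 and 89 (42 higher, 47 lower) scaled to the spike-ins.

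The fourth question was what changed between 3 and 5 divisions. Prdm1, which encodes the plasma cell transcription factor BLIMP1, rose from 6.81 ± 3.01 to 21.8 ± 5.98 CPM (3.12-fold, adjusted p = 0.000414), and Xbp1 rose from 102.6 ± 12.3 to 156.3 ± 14.6 (1.52-fold). Zbtb32 rose from 107.1 ± 36.8 to 311.1 ± 50.7 CPM (2.89-fold) and the transcription factor gene Bhlhe41 from 23.2 to 93.02 ± 12.2 (3.99-fold). Gstt1 (5.83-fold) and Gstt3 (4.97-fold), 2 similar glutathione transferase genes whose reads are not fully separable, and Pik3r6 (4.81-fold, a subunit of PI3 kinase gamma) also rose. Sidt1 (3.25-fold), Abca1 (3.2-fold), Fcgrt (3.01-fold, the neonatal Fc receptor) and Marco (2.96-fold, a scavenger receptor) were lower. Irf4 (adjusted p = 0.0516), Sdc1 (0.0695) and Dnmt3a (0.0945) did not pass, but did with the host as a block (0.0210, 0.0429 and 0.0345). All 46 mitosis genes rose, 46 also over the list alone, with Aurka at 1.6-fold and Ccnb1 at 1.57-fold (camera adjusted p = 8.8e-28, and adjusted p = 0.335 with an estimated correlation). Of 41 DNA replication genes 34 rose and 0 fell (37 over the list alone; Mcm10 at 1.57-fold, camera adjusted p = 2.6e-18, and adjusted p = 0.335 with an estimated correlation). Oxidative phosphorylation had 36 higher and 0 lower of 56 (41 over the list alone; Cycs, cytochrome c, at 1.40-fold, camera adjusted p = 1.8e-12, and adjusted p = 0.335 with an estimated correlation). The unfolded protein response and ER secretion list had 34 higher and 0 lower of 63 (38 and 1 over the list alone; the chaperone genes Sdf2l1 at 1.71-fold and Hsp90b1 at 1.55-fold, camera adjusted p = 6.7e-12, and adjusted p = 0.364 with an estimated correlation). MYC and ribosome biogenesis had 17 higher and 1 lower of 41 (28 and 1 over the list alone, camera adjusted p = 1.5e-08), and glycolysis 10 and 1 of 21 (12 and 2; Hk2 at 1.51-fold; 0.00018). Class switching had 8 higher and 0 lower of 16 (9 and 0, camera adjusted p = 0.0029) and the plasma cell list 9 and 4 of 26 (11 and 6; Igj, the antibody joining chain, at 3.2-fold; 0.037). With an estimated correlation these 4 lists were at adjusted p = 0.364, 0.364, 0.335 and 0.364, and the plasma cell list did not pass without Div5 of host 197 (0.0732), Div8pos of host 196 (0.0528) or Div8pos of host 197 (0.0550).

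In the same step B cell genes fell relative to all genes but not per cell. The B cell identity list had 1 higher and 17 lower of 30 (1 and 19 over the list alone, camera adjusted p = 2.0e-06, and adjusted p = 0.335 with an estimated correlation). Its median of -0.21 flipped to +0.33 per cell. Faim3 (1.88-fold lower), Fcer2a (1.76-fold lower, the low-affinity IgE receptor) and the repressor gene Bach2 (1.63-fold lower) did not pass per cell (adjusted p = 0.152, 0.280 and 0.492). The MHC class II list had 0 higher and 8 lower of 12 (10 over the list alone, camera adjusted p = 2.4e-05, and adjusted p = 0.364 with an estimated correlation). Its median of -0.24 flipped to +0.3 per cell, with 0 of 12 genes called either way (camera adjusted p = 0.0523 with spike-in scaling). Within that list H2-Oa was 1.47-fold lower (per cell adjusted p = 0.961) and H2-Ob 1.32-fold lower, which flipped to a log2 value of 0.14 per cell that did not pass (adjusted p = 0.576). The interferon list had 1 higher and 17 lower of 41 (1 and 20 over the list alone, camera adjusted p = 2.6e-05, and adjusted p = 0.364 with an estimated correlation). Oasl2 was 1.67-fold lower (per cell adjusted p = 0.417), and the list median of -0.31 flipped to +0.22 per cell. The NF-kB and TLR list had 3 higher and 13 lower of 39 (4 and 14 over the list alone, camera adjusted p = 0.0018, and adjusted p = 0.335 with an estimated correlation, per cell 0.400). Cd83 was 1.45-fold lower and Rel 1.39-fold lower, and both flipped per cell, to log2 values of 0.0065 and 0.073 that did not pass (adjusted p = 0.982 and 0.781). Quiescence and recirculation had 2 higher and 7 lower of 26 with a median of -0.15 that flipped to +0.39 per cell (camera adjusted p = 0.026, and adjusted p = 0.364 with an estimated correlation; 0.330 per cell, 0.259 without Div5 of host 196 and 0.206 without Div3 of host 197). The marginal zone and B1 list (5 and 1 of 13, camera adjusted p = 0.083) did not pass. By edgeR 3199 genes differed (1710 higher, 1489 lower; 254 by a log2 fold change of 1 or more), against 5446 higher and 48 lower scaled to the spike-ins. The count was 1522 without Div3 of host 196 and 1200 without Div5 of host 197.

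The fifth question was what changed from 5 divisions to 8 or more in CD138-negative cells. Slpi, which encodes a secreted protease inhibitor, rose from 4.73 ± 1.01 to 87.73 ± 13.5 CPM (18.6-fold, adjusted p = 6.85e-09). Prdm1 rose from 21.8 ± 5.98 to 58.39 ± 10.6 CPM (2.68-fold, adjusted p = 1.46e-05), Xbp1 from 156.3 ± 14.6 to 262.1 ± 27.2 (1.68-fold) and Irf4, a transcription factor needed for plasma cells, from 154.5 ± 12.9 to 240 ± 18.7 (1.55-fold). An entry without a symbol (Entrez 239151; 15.8-fold), Anxa2 (10.8-fold, annexin A2, from 2.89 to 31.24 ± 2.07 CPM) and Cdkn2a (9.35-fold, the locus of the cell cycle inhibitor p16) also rose. Grm6, which encodes a glutamate receptor, fell from 57.93 ± 3.77 to 3.54 ± 0.029 CPM (16.3-fold lower), and Aire (9.75-fold), Fam101b (8.46-fold) and Shank1 (8.37-fold) were lower too. Bach2 fell from 59.77 to 24.44 ± 2.41 CPM (2.45-fold lower). Pax5, the transcription factor that holds B cell identity, fell from 343.6 to 236.6 (1.45-fold lower, per cell log2 -0.05, adjusted p = 0.867). Dnmt3a was 1.32-fold lower relative to all genes and flipped to a log2 value of 0.08 per cell that did not pass (adjusted p = 0.776), while Dnmt1, the maintenance methyltransferase gene, rose 1.33-fold and its partner Uhrf1 1.42-fold. The genes Sdc1 (adjusted p = 0.377) and Myc (0.535) did not pass.

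B cell identity genes fell as a group in this step, with 1 higher and 27 lower of 30 (2 and 27 over the list alone, camera adjusted p = 1.1e-11, and adjusted p = 0.172 with an estimated correlation). Among them were Fcer2a (3.97-fold), the complement receptor gene Cr2 (3.71-fold) and Faim3 (3.48-fold). All 12 MHC class II genes fell, also over the list alone (H2-Oa 2.89-fold, H2-Ob 2.65-fold, camera adjusted p = 4.5e-07, and adjusted p = 0.283 with an estimated correlation), and their transactivator Ciita was 1.77-fold lower (per cell adjusted p = 0.215). The medians of these 2 lists were -0.55 and -0.56, and -0.06 per cell in both. The plasma cell list had 17 higher and 2 lower of 26, the same over the list alone (Igj 2.84-fold, Eaf2 2.81-fold, Il6ra 2.50-fold, camera adjusted p = 1.7e-05, and adjusted p = 0.283 with an estimated correlation). The unfolded protein response and ER secretion list had 55 higher and 1 lower of 63, also over the list alone (Sec24d 3.83-fold, a coat protein of vesicles leaving the ER; Derl3 2.11-fold; Lman1 2.01-fold, camera adjusted p = 9.2e-15, and adjusted p = 0.283 with an estimated correlation). DNA replication had 37 higher and 0 lower of 41, also over the list alone (Ccne1 2.16-fold and Ccne2 2.10-fold, the E cyclins, camera adjusted p = 1.3e-13), and MYC and ribosome biogenesis 38 and 0 of 41 (Rrs1 1.71-fold; 8.5e-13). Oxidative phosphorylation had 46 and 1 of 56 (49 and 1 over the list alone; Cycs 1.63-fold, camera adjusted p = 3.3e-11). Mitosis had 35 and 1 of 46 (37 and 1 over the list alone; 2.9e-07), glycolysis 14 and 1 of 21 (15 and 1; Hk2 2.26-fold; 1.7e-05) and class switching 12 and 1 of 16 (Ung 1.92-fold, a uracil glycosylase; 0.0014). With an estimated correlation these 6 lists were at adjusted p = 0.283, 0.283, 0.283, 0.408, 0.283 and 0.283. The interferon list had 3 higher and 25 lower of 41 (Oas1b 2.29-fold lower). Its median of -0.48 flipped to +0.02 per cell (camera adjusted p = 6.4e-06, and adjusted p = 0.364 with an estimated correlation). The NF-kB and TLR list had 5 higher and 23 lower of 39 (camera adjusted p = 0.00016, and adjusted p = 0.170 with an estimated correlation). Its median of -0.35 flipped to +0.15 per cell, with 8 genes higher and 1 lower (camera adjusted p = 0.0518 with spike-in scaling). Quiescence and recirculation had 4 higher and 11 lower of 26 (5 and 12 over the list alone, camera adjusted p = 0.006, and adjusted p = 0.314 with an estimated correlation). Its median of -0.31 flipped to +0.20 per cell. By edgeR 6433 genes differed (3231 higher, 3202 lower; 926 by a log2 fold change of 1 or more), against 5095 higher and 369 lower scaled to the spike-ins.

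The sixth question compared the ends of the range in CD138-negative cells, Div8neg against Div0. Prdm1 rose from 6.45 ± 2.49 to 58.39 ± 10.6 CPM (9.18-fold, adjusted p = 7.4e-09). Il10, which encodes an immunosuppressive cytokine, rose from 0.805 ± 0.191 to 18.83 ± 2.56 CPM (23.3-fold). Dkk3 (85.9-fold, a secreted relative of Wnt inhibitors, to 17.94 ± 4.36 CPM), Itga8 (48.1-fold, an integrin chain), Slc6a12 (35.5-fold, a betaine and GABA transporter), Pik3r6 (25.4-fold, to 119.6 ± 6.13), Gstt1 (24.9-fold), Cdkn2a (24.1-fold), Gstt3 (22.0-fold) and Zdhhc2 (20.6-fold, a palmitoyltransferase) also rose. Zfp318, which encodes a regulator of IgD splicing, fell from 289.5 ± 17 to 10.73 ± 0.385 CPM (27.0-fold lower). The other large falls were in Mapk12 (52.6-fold), Abca1 (21.3-fold), Ell3 (20-fold, an elongation factor), Rasgef1b (19.7-fold), Rapgef4 (19.6-fold, a cyclic AMP sensor), Sidt1 (19.1-fold), Neurl3 (17.1-fold), Kcng1 (15.6-fold, a potassium channel subunit) and Pydc3 (14.9-fold, an interferon-inducible gene). Bach2 fell from 145 ± 6.63 to 24.44 ± 2.41 CPM (5.95-fold lower, log2 -0.88 per cell). Pax5 was 1.61-fold lower and Myc 1.30-fold lower relative to all genes, and both flipped per cell, to log2 values of 1.00 and 1.29. The methylation genes Uhrf1 (2.65-fold), Dnmt1 (1.73-fold) and Dnmt3a (1.22-fold) rose and so did Xbp1 (2.21-fold), whereas Sdc1 did not pass (adjusted p = 0.745). Irf4 passed with the host as a block but not without it (adjusted p = 0.0243 and 0.0526), as lower relative to all genes, and flipped per cell to a log2 value of 1.55.

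All 46 mitosis genes were higher in Div8neg than in Div0, 46 also over the list alone (Ccnb1 4.81-fold, Plk1 4.42-fold, camera adjusted p = 1.6e-22, and adjusted p = 0.296 with an estimated correlation). DNA replication had 38 higher and 1 lower of 41 (Ccne1 4.29-fold, Mcm10 4.02-fold, camera adjusted p = 1.5e-13) and oxidative phosphorylation 54 and 1 of 56 (Cycs 2.15-fold; 1.8e-13). MYC and ribosome biogenesis had 38 and 1 of 41 (camera adjusted p = 1.9e-08) and glycolysis 16 and 3 of 21 (the lactate transporter gene Slc16a1 3.03-fold and Hk2 2.89-fold; 0.00028), and all 4 had the same counts over the list alone. With an estimated correlation these 4 lists were at adjusted p = 0.329, 0.329, 0.384 and 0.329. The unfolded protein response and ER secretion list had 55 higher and 2 lower of 63 (56 and 2 over the list alone; Derl3 8.47-fold, camera adjusted p = 5.8e-12, and adjusted p = 0.348 with an estimated correlation). In class switching 12 rose and 1 fell of 16 (Exo1 3.06-fold, Ung 2.37-fold, camera adjusted p = 0.0013, and adjusted p = 0.296 with an estimated correlation). In the marginal zone and B1 list 8 rose and 4 fell of 13 (Bhlhe41 15.9-fold, Zbtb32 14.1-fold to 492.7 ± 25.9 CPM, Spn 10-fold, camera adjusted p = 0.410). The plasma cell list had 15 higher and 5 lower of 26 (15 and 6 over the list alone; Igj 4.39-fold, camera adjusted p = 0.034, and adjusted p = 0.386 with an estimated correlation), and was not called without Div8neg of host 197 (0.0637). The B cell identity list had 1 higher and 27 lower of 30 (2 and 27 over the list alone; Faim3 11.9-fold, from 499.1 to 42.16 ± 5.77 CPM; Cr2 7.73-fold; Fcer2a 7.49-fold, camera adjusted p = 1.0e-08, and adjusted p = 0.296 with an estimated correlation). Its median of -0.66 flipped to +1.02 per cell although Faim3 stayed lower at -1.87. All 12 MHC class II genes were lower (H2-Oa 4.57-fold, still lower per cell at -0.51, camera adjusted p = 2.5e-06, and adjusted p = 0.329 with an estimated correlation). Their median of -0.87 flipped to +0.81 per cell. Interferon genes had 5 higher and 27 lower of 41 (5 and 28 over the list alone; Rtp4 9.38-fold lower, Oas2 5.58-fold lower, camera adjusted p = 0.00013, and adjusted p = 0.407 with an estimated correlation). Its median of -0.79 flipped to +0.89 per cell. Quiescence and recirculation had 4 higher and 20 lower of 26 (5 and 20 over the list alone; Pik3ip1 5.30-fold lower, camera adjusted p = 0.00033, and adjusted p = 0.329 with an estimated correlation). Its median of -0.83 flipped to +0.85 per cell. The NF-kB and TLR list had 8 higher and 26 lower of 39 (9 and 26 over the list alone, camera adjusted p = 0.0045, and adjusted p = 0.296 with an estimated correlation). Relative to all genes its median was -0.45 but its mean +0.03. Per cell the median flipped to +1.23, with 36 of 39 genes higher and 0 lower. With spike-in scaling camera, which compares the list with all other genes, gave adjusted p = 0.654. Chromatin regulators (14 and 11 of 27, camera adjusted p = 0.420) and apoptosis (9 and 7 of 20; 0.580) did not pass as lists. By edgeR 8554 genes differed (4257 higher, 4297 lower; 2590 by a log2 fold change of 1 or more), against 10742 higher and 191 lower scaled to the spike-ins.

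The seventh question was which genes changed with the number of divisions from 0 to 8 in CD138-negative cells, by a linear slope. A slope does not show that the steps were even. Prdm1 rose by 0.45 per division on the log2 scale (SE 0.047, adjusted p = 1.05e-05), although it was at 6.45, 5.11 and 6.81 CPM in Div0, Div1 and Div3 before 21.8 in Div5 and 58.39 in Div8neg. Bach2 fell by 0.31 per division (SE 0.021, adjusted p = 6.87e-07; by 0.13 per cell). Among genes with at least 10 CPM in the higher group the steepest rises were in Dkk3 (0.83), Itga8 (0.82) and Cdkn2a (0.73), and the steepest falls in Mapk12 (-0.79), Abca1 (-0.61), Zfp318 (-0.56) and Ell3 (-0.53). Uhrf1 rose by 0.17, Xbp1 by 0.16 and Dnmt1 by 0.09 per division. Pax5 (-0.08) and Myc (-0.06) fell relative to all genes and flipped per cell, to 0.10 and 0.12 per division. With the Div8pos libraries added at 8 divisions Pax5 did not pass (adjusted p = 0.139). Irf4 did not pass (-0.02, adjusted p = 0.525) and flipped per cell to 0.16 per division, and with the Div8pos libraries added to 0.20 (adjusted p = 0.0299). Sdc1 (0.06, adjusted p = 0.430) passed with the Div8pos libraries added (0.00374) and Dnmt3a (0.02; 0.669) did not pass. By edgeR 7753 of 11836 genes changed with division (3891 rising, 3862 falling; 2449 by 0.125 or more per division on the log2 scale), against 9821 rising and 209 falling scaled to the spike-ins. Cells at 8 or more divisions were entered as 8.

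The eighth question compared CD138-positive with CD138-negative cells at 8 or more divisions. Sdc1, which encodes CD138, rose from 4.72 ± 1.65 to 320.3 ± 15.2 CPM (68.4-fold, log2 6.10, SE 0.17, adjusted p = 4.02e-14), as the sort required. Among the other anchor genes, Xbp1 rose from 262.1 ± 27.2 to 1624 ± 51.6 (6.20-fold, adjusted p = 3.74e-13), Prdm1 from 58.39 ± 10.6 to 324.8 ± 6.10 (5.57-fold, adjusted p = 5.4e-10) and Irf4 from 240 ± 18.7 to 1191 ± 34.2 CPM (4.96-fold, adjusted p = 4.02e-14). Pax5 fell from 236.6 ± 6.81 to 9.46 ± 0.184 CPM (25.0-fold lower, log2 -4.64, SE 0.084, adjusted p = 3.28e-16) and Bach2 from 24.44 ± 2.41 to 0.340 ± 0.142 (70.8-fold lower). That last Bach2 level was close to the floor, with 3 counts in the lower library. Dnmt3a fell from 173.5 ± 9.30 to 37.88 ± 1.22 CPM (4.58-fold lower, adjusted p = 6.03e-13). Uhrf1 (1.31-fold lower, adjusted p = 0.00144) and Dnmt1 (1.15-fold lower; 0.00829, and 0.121 without Div8pos of host 197) were lower relative to all genes and flipped per cell, to log2 values of 0.20 and 0.38 that did not pass (adjusted p = 0.433 and 0.118). Myc passed with the host as a block but not without it (adjusted p = 0.0149 and 0.0676).

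**Figure D3:**
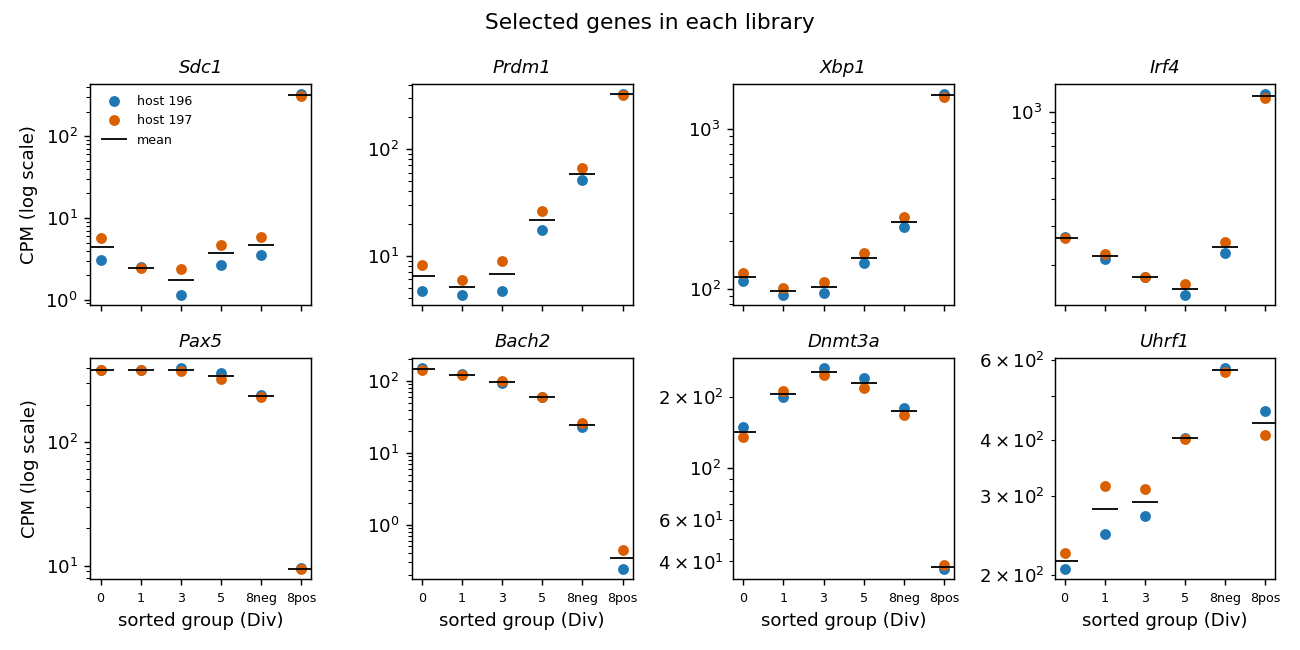
CPM of Sdc1, Prdm1, Xbp1, Irf4, Pax5, Bach2, Dnmt3a and Uhrf1 by group, with 1 point per host and the mean as a dash (log axis). Per cell Pax5 flipped to higher in Div8neg than in Div0 (log2 1.00) and Uhrf1 in Div8pos against Div8neg to 0.20, which did not pass (adjusted p = 0.433).

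Other large rises in Div8pos, among genes with at least 10 CPM in the higher group, were in Creg2 (103-fold), Chst1 (69.4-fold, a sulfotransferase), Prlr (69.1-fold, the prolactin receptor), Gpnmb (66.0-fold), Ak7 (65.8-fold, an adenylate kinase), Cacna1h (64.5-fold, a calcium channel subunit), Dusp9 (46.2-fold, a phosphatase of MAP kinases) and Epcam (41.9-fold, an epithelial adhesion molecule, from 1.70 to 72.03 ± 7.47 CPM). Mt2, a metallothionein gene, rose 124-fold but differed between hosts by more than its mean (19.42 ± 21.4 CPM). Itga8 (at least 94.6-fold lower) and Zeb2os (at least 80.3-fold lower, a gene antisense to Zeb2, with the use of strand in counting not given) had 0 counts in Div8pos, against a floor of 3 counts over the group. Slc6a12 (1 count in Div8pos; 253-fold lower, counting interval 55.6 to 12300), Gbp2b (2 counts; 235-fold, 72.3 to 2170; near copy of Gbp2), Gapt (2 counts; 211-fold, 65 to 1950) and Cyp8b1 (1 count; 207-fold, 45.2 to 10100) were close to the floor, and these intervals hold counting error alone. Ms4a4c (248-fold lower), the DNA sensor gene Tlr9 (176-fold lower, from 333.9 ± 9.13 to 1.89 ± 0.0696 CPM) and Myo1f (162-fold lower, a myosin) fell from higher levels. Spib, which encodes an ETS transcription factor of B cells, fell from 614.7 ± 35.4 to 6.35 CPM (96.4-fold lower).

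Of 26 plasma cell genes 24 rose and 2 fell, the same over the list alone, among them Cd28 (40.2-fold, a costimulatory receptor, to 37.13 ± 7.39 CPM), Fkbp11 (18.9-fold, a prolyl isomerase of the ER), Eaf2 (14.9-fold) and Igj (11.7-fold, from 141.4 ± 31.3 to 1652 ± 165). The camera test of the plasma cell list gave adjusted p = 3.4e-08, and adjusted p = 0.0805 with an estimated correlation. The unfolded protein response and ER secretion list had 62 higher and 0 lower of 63, also over the list alone (Sec24d 11.6-fold; Ern1 6.75-fold, the sensor IRE1; Srprb 6.57-fold; Txndc11 5.98-fold, camera adjusted p = 2.3e-22, and adjusted p = 0.319 with an estimated correlation). Its summed level went from 17730 ± 2040 to 45630 ± 3530 CPM. B cell identity had 2 higher and 28 lower of 30, also over the list alone (Cd22 49.5-fold lower, an inhibitory receptor, from 1875 to 37.72 CPM; Fcer2a 36.0-fold, camera adjusted p = 1.2e-13, and adjusted p = 0.077 with an estimated correlation). Its summed level went from 13780 ± 341 to 3893 ± 14.5. All 12 MHC class II genes were lower (H2-Oa 39.7-fold, Ciita 18.6-fold, H2-Ob 8.44-fold, camera adjusted p = 1.1e-06, and adjusted p = 0.415 with an estimated correlation). The NF-kB and TLR list had 3 higher and 30 lower of 39, also over the list alone (Cd86 35.9-fold, Cd83 11.8-fold, Tnf 11.1-fold and Traf1 9-fold lower, camera adjusted p = 5.9e-08, and adjusted p = 0.0278 with an estimated correlation). Marginal zone and B1 genes had 2 higher and 11 lower of 13 (S1pr3 74.7-fold, Asb2 80.8-fold and Zbtb32 24.2-fold lower, camera adjusted p = 0.00014, and adjusted p = 0.0582 with an estimated correlation). Interferon genes had 5 higher and 29 lower of 41 (Oas1a 33.3-fold lower, whose reads can also come from Oas1b; Herc6 9.36-fold lower, camera adjusted p = 2.5e-05, and adjusted p = 0.470 with an estimated correlation). These 4 falling lists stayed below 0 per cell, with medians of -0.81 (MHC class II), -0.63 (NF-kB and TLR), -2.03 (marginal zone and B1) and -0.66 (interferon). MYC and ribosome biogenesis (37 higher and 1 lower of 41; Gnl3 2.64-fold, camera adjusted p = 9.0e-08) and oxidative phosphorylation (43 and 0 of 56; Sdhc 1.90-fold; 1.1e-06) rose further. DNA replication (31 and 4 of 41; Ccne2 2.32-fold, Rrm2 2.15-fold; 0.00025) and mitosis (30 and 3 of 46; Cdc25b 1.83-fold, Cdk1 1.80-fold, Mki67 1.66-fold; 0.00056) did too, and all 4 counts were the same over the list alone. With an estimated correlation these 4 lists were at adjusted p = 0.470, 0.470, 0.610 and 0.610. Glycolysis (12 and 9 of 21, camera adjusted p = 0.380; Hk2 3.68-fold) and class switching (8 and 4 of 16; 0.450; the ligase gene Lig4 3.02-fold) did not pass as lists. Nor did chromatin regulators (10 and 11 of 27, camera adjusted p = 0.980; Tet3 2.39-fold lower), quiescence (11 and 12 of 26; 0.350; Ccr7 24.7-fold lower) and apoptosis (7 and 11 of 20; 0.3; Fas 4.79-fold and Bcl2 4.03-fold lower). The quiescence median of -0.16 and the apoptosis median of -0.27 flipped per cell to +0.42 and +0.32. By edgeR 8674 genes differed (4417 higher, 4257 lower; 3313 by a log2 fold change of 1 or more, 1209 higher and 2104 lower), against 6241 higher and 1761 lower scaled to the spike-ins. As groups differed in most genes, relative changes here also carry the weight of the genes that rose most.

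**Figure D4:**
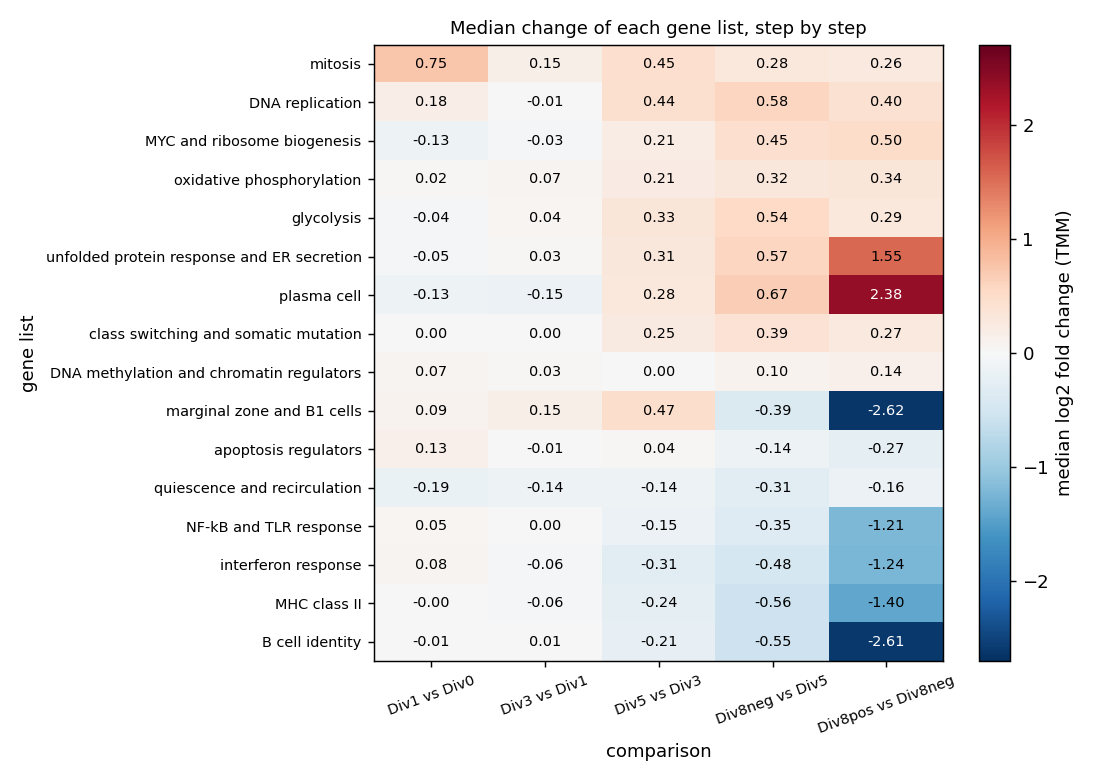
Median log2 fold change of 16 gene lists in 5 steps, relative to all genes; some negative medians turn positive per cell. The mitosis list was above 0 in each step, with medians of 0.75, 0.15, 0.45, 0.28 and 0.26.

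The ninth question compared Div8pos with Div0, the cells farthest apart. Sdc1 (74.3-fold), Prdm1 (51.2-fold), Xbp1 (13.7-fold) and Irf4 (4.49-fold) were higher, and Bach2 (421-fold) and Pax5 (40.2-fold) lower. Bach2 was close to the floor in Div8pos (0.340 ± 0.142 CPM, with 3 counts in the lower library), so its fold is imprecise. Chst1 (189-fold) and Dusp9 (150-fold) rose among genes away from the floor, with Evc (3 counts in Div0; 252-fold, counting interval 92.9 to 1320) and Chrnb4 (1 count; 222-fold, 48.9 to 10900) near it. Rapgef4 (at least 235-fold), Pydc4 (at least 142-fold) and Sema5a (at least 81.3-fold) were lower with 0 counts in Div8pos, and Map3k19 was 621-fold lower with 2 counts (191 to 5720). Dnmt3a was 3.77-fold lower, which flipped per cell to a log2 value of 0.36 that did not pass (adjusted p = 0.132), while Uhrf1 (2.03-fold) and Dnmt1 (1.51-fold) were higher. Myc passed with the host as a block but not without it (adjusted p = 0.0223 and 0.0796). The plasma cell list had 24 higher and 1 lower of 26 (24 and 2 over the list alone; Fkbp11 87.0-fold, camera adjusted p = 4.0e-07, and adjusted p = 0.163 with an estimated correlation). Of 63 genes for the unfolded protein response and ER secretion 62 were higher and 0 lower (camera adjusted p = 5.4e-19, and adjusted p = 0.301 with an estimated correlation). B cell identity had 1 higher and 28 lower of 30 (Fcer2a 269-fold, Spib 166-fold, camera adjusted p = 9.8e-12, and adjusted p = 0.163 with an estimated correlation) and stayed below 0 per cell (median -3.65, and -1.37 per cell). MHC class II had 12 of 12 lower (H2-Oa 182-fold, Ciita 32.3-fold, camera adjusted p = 1.5e-06, and adjusted p = 0.301 with an estimated correlation). Its median of -2.15 flipped to +0.12 per cell. The NF-kB and TLR list had 5 higher and 32 lower of 39 (camera adjusted p = 9.3e-07, and adjusted p = 0.0499 with an estimated correlation), with a median of -1.95 that flipped to +0.29 per cell. Interferon genes had 4 higher and 35 lower of 41 (camera adjusted p = 1.2e-06, and adjusted p = 0.301 with an estimated correlation; median -2.31, and -0.06 per cell). Mitosis (46 of 46 higher, camera adjusted p = 7.6e-16), DNA replication (39 higher and 2 lower of 41; 9.5e-11), MYC and ribosome biogenesis (39 and 0 of 41; 8.4e-10) and oxidative phosphorylation (55 and 0 of 56; 2.1e-12) were higher. With an estimated correlation each of these 4 lists was at adjusted p = 0.301. Also higher was class switching (12 and 3 of 16, camera adjusted p = 0.026, and adjusted p = 0.301 with an estimated correlation). Marginal zone and B1 genes had 3 higher and 10 lower of 13 (camera adjusted p = 0.029, and adjusted p = 0.256 with an estimated correlation). Quiescence genes had 5 higher and 16 lower of 26 (camera adjusted p = 0.0054, and adjusted p = 0.301 with an estimated correlation). Its median of -1.08 flipped to +1.17 per cell. Glycolysis had 13 higher and 6 lower of 21 (camera adjusted p = 0.039, and adjusted p = 0.519 with an estimated correlation; 0.0586 without Div8pos of host 196). By edgeR 9927 genes differed (4846 higher, 5081 lower; 5492 by a log2 fold change of 1 or more), against 9968 higher and 739 lower scaled to the spike-ins.

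Genes that mark other blood cells were present at low summed levels. Dendritic cell markers went from 100.3 ± 7.33 CPM in Div0 to 298.6 ± 0.299 in Div1 and 462.1 ± 7.16 in Div3, and down to 200.7 ± 12.4 in Div8neg and 31.13 ± 3.64 in Div8pos. Flt3 alone held 89.6% of these counts in Div0 and 93.8% in Div1. That list was called in Div1 against Div0 (3 higher, 0 lower of 7, camera adjusted p = 0.037, and adjusted p = 0.387 with an estimated correlation). It was not called with spike-in scaling or without a filter on low counts (camera adjusted p = 0.133 and 0.169), nor without Div0 or Div1 of host 196. Per cell 4 of the 7 were higher and 0 lower. In Div3 against Div1 it was called as well (2 and 0 of 7; 0.0065, and adjusted p = 0.274 with an estimated correlation), but not without Div3 of host 196 (0.103) or without the filter (0.0935). Monocyte markers were at 360 ± 0.495 CPM in Div0, 699 ± 34.5 in Div3, 541.3 ± 33.1 in Div8neg and 69.59 ± 1.06 in Div8pos. Mpeg1 alone held 58.7% of these counts in Div0 and 79.3% in Div3, and in Div3 against Div1 1 gene was higher and 1 lower of 19. In Div8neg against Div0 5 were higher and 10 lower (median -1.21, which flipped to +0.48 per cell). As a list they were called in Div8pos against Div0 alone (1 higher, 13 lower of 19, camera adjusted p = 0.026, and adjusted p = 0.373 with an estimated correlation). Their median of -1.69 flipped to +0.63 per cell. Platelet markers went from 129.1 ± 11.6 in Div0 to 55.72 ± 5.92 in Div8neg and 103.9 ± 6.89 in Div8pos, and Itgb3 alone held 87.4, 73 and 96.5% of these counts. They were called in Div5 against Div3 (0 and 2 of 8, camera adjusted p = 0.044, and adjusted p = 0.446 with an estimated correlation; 0.0514 without a filter on low counts). That platelet call also ended without Div3 of host 196 (0.195), Div5 of host 196 (0.0635) or either Div8pos library (0.0528 and 0.0525). The T cell, neutrophil and erythroid lists were not called in any comparison with all libraries, no block and TMM scaling (smallest camera adjusted p of 0.110, 0.400 and 0.320). With spike-in scaling camera called each in 4 comparisons. As camera compares a list with all other genes, these calls do not show a change per cell. The erythroid list was called in Div1 against Div0 with the host as a block (0.0433), without Div1 of host 196 (0.0171) or without Div0 of host 197 (0.0165). The neutrophil list was called higher there without Div1 of host 196 (0.000342) or Div0 of host 197 (0.0274), and lower without Div1 of host 197 (0.0481). In Div3 against Div1 it was called lower without Div1 of host 196 (5.93e-07) or Div3 of host 197 (0.0495), and higher without Div1 of host 197 (0.0290). The T cell list was called in Div3 against Div1 without Div3 of host 196 (0.0491) and in Div5 against Div3 without Div3 of host 197 (0.0397). T cell markers were at 236.2 ± 3.97 CPM in Div0, 218.6 ± 22.3 in Div8neg and 90.64 ± 5.82 in Div8pos. Neutrophil markers were at 43.39 ± 27.6 in Div0 and 65.42 ± 59.4 in Div1, where host 197 held 107.4 and host 196 held 23.39. Erythroid markers were at 62.86 ± 53.4 in Div0, with 100.6 in host 196 and 25.1 in host 197, and 5 of the 6 tested were lower in Div8pos than in Div0. Natural killer markers, with 3 genes tested and so no list test, went from 40.27 ± 9.52 CPM in Div0 to 239.1 ± 9.93 in Div8neg and 12.29 ± 2.52 in Div8pos. Tbx21 alone held 70.8, 96.3 and 64.1% of these counts, and it was the only 1 of the 3 called in Div8neg against Div0. Of the 16 genes in the list of immunoglobulin constant and joining genes, 2 were in the deposited table and only Vpreb3 was tested. The heavy and light chain constant genes looked for, such as Ighm and Igkc, were not found in that table. Antibody classes could therefore not be told apart here, and CPM values and totals per cell leave these genes out.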

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

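Tests with single libraries left out were planned before the data were examined; none of the alternatives below was added after the results were seen. Of 601 results for named genes 555 were called. Of these, 412 were called under every alternative tried on named genes and 143 were not under at least 1. The minimum fold was not among the alternatives tried on named genes, and smaller changes would be lost under it. Outside spike-in scaling, left-out libraries and fits of 2 groups, 13 of these 143 were lost. Size factors from DESeq2 left 595 of the gene results on the same side (5 weaker, 1 stronger), the DESeq2 Wald test 586 (10 weaker, 2 stronger), the stricter filter 594 (1 weaker), no filter 583 (18 stronger) and fits of 2 groups 566 (12 weaker, 4 stronger). The cause was not tested for any change below unless it is given.

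A minimum fold left 119 genes in Div1 against Div0, 77 in Div3 against Div1, 254 in Div5 against Div3, 926 in Div8neg against Div5, 2590 in Div8neg against Div0, 3313 in Div8pos against Div8neg and 5492 in Div8pos against Div0, and 2449 for the slope, since it asks for more than any change. Spike-in scaling gave 9838, 89 and 5494 genes in the first 3 of these. In Div3 against Div1 no filter gave 740 genes and the 2 groups alone 178. Of 154 list tests 81 were called (47 up, 34 down) and 2 with an estimated correlation, which widens the test. Spike-in scaling called 97, no filter 78 and the stricter filter 81.

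Hosts pair the libraries across groups. The replicate block for hosts moved Div1 against Div0 to 1713 genes and Div3 against Div1 to 755. Among named genes it added calls in Div1 against Div0 (Xbp1 0.00617, H2-Ob 0.0336, Rrp9 0.0225, Ngp 0.00127, Hba-a2 0.00211), Div3 against Div1 (H2-Oa 0.0236, Atf6 0.0291, Rtp4 0.0214, Pik3ip1 0.0126, Vpreb3 0.00776, Lcn2 8.95e-05, Itgb3 0.0111), Div5 against Div3 (Sdc1 0.0429, Irf4 0.0210, Dnmt3a 0.0345), Div8neg against Div0 (Irf4 0.0243, Hba-a2 4.39e-06), and for Myc in Div8pos against Div8neg (0.0149) and Div0 (0.0223). Without a filter Xbp1, Irf4, Sdc1 and Myc gained these calls too. The block added 3 list calls (erythroid in Div1 against Div0 0.0433, MHC class II 0.0225 and platelet 0.0496 in Div3 against Div1). It changed no other call of a named gene or planned list, and was not run for the families chosen after values were seen. Counts of called list members are given without the block and can differ with it. In Div1 against Div0 it gave 2 higher and 11 lower for quiescence, and 1 higher and 6 lower for the unfolded protein response list. For the totals no fit with a block was run, but their ratios were taken within hosts and their permutations stayed within hosts.

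With each library left out in turn the counts ranged from 624 to 1213 (Div1 against Div0), 138 to 405 (Div3 against Div1), 1200 to 3248 (Div5 against Div3), 4782 to 6489 (Div8neg against Div5), 7565 to 8678 (Div8neg against Div0), 7846 to 8773 (Div8pos against Div8neg), 9418 to 10075 (Div8pos against Div0) and 6640 to 7903 (slope), and per cell from 840 to 10272, 10410 to 11051 and 6520 to 8968. The total mRNA correlation ranged from 0.846 to 0.888, the ratio of Div1 to Div0 from 1.41 to 1.97, of Div8neg to Div0 from 2.99 to 3.66 and of Div8pos to Div8neg from 1.52 to 1.74, and list calls from 80 to 86. A lone library was assumed to vary like the other groups. Among gene results so made 6960 kept their side, 172 were weaker and 46 stronger. List tests without Div1 of host 197 reversed for neutrophil markers in Div1 against Div0 (0.0481, over all left-out libraries 0.000342 to 0.571) and in Div3 against Div1 (0.0290, 5.93e-07 to 0.956) and for DNA replication in Div3 against Div1 (0.00745, 2.54e-05 to 0.76).

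Spike-in scaling reversed 58 gene results (counted where either value was called), 58 were weaker, 17 stronger and 468 on the same side, since the shift in total mRNA is added to each gene. Log2 values so scaled in Div1 against Div0 were Irf4 0.47, Bach2 0.50, Cd55 0.076, Faim3 0.34, Ets1 0.35, Itgb7 0.066, Lax1 0.44, Sec23b 0.52, Sec13 0.54, Aldoa 0.37, Pfkl 0.47, Zfp36l2 0.060, Klf2 0.091, S1pr1 0.22, Txnip 0.47 and Vpreb3 0.11. In Div5 against Div3 they were Pax5 0.38, Myc 0.25, H2-Eb2 0.080, H2-Ob 0.14, H2-DMa 0.26, Cd83 0.0065, Rel 0.073, Nfkbie 0.13, Ltb 0.18, Foxo1 0.045, Btg1 0.12 and Mpeg1 0.36, and in Div8neg against Div5 Dnmt3a 0.083 and Bcl2l2 0.066. In Div8neg against Div0 they were Irf4 1.55, Pax5 1.00, Myc 1.29, H2-Eb2 0.24, H2-DMa 0.76, Cd83 0.15, Rel 0.46, Nfkbie 0.56, Ltb 0.71, Cd247 0.97, Cd2 1.43, Apoe 0.030 and Itgb3 0.22. In Div8pos against Div8neg they were Dnmt1 0.38 and Uhrf1 0.20, and in Div8pos against Div0 Myc 2.07, Dnmt3a 0.36, Casp9 0.66, Fas 1.28, Xiap 1.37, Vpreb3 1.95, Tbx21 0.43, Marco 0.082, Apoe 0.063 and Flt3 0.11. Slopes so scaled were Irf4 0.16, Pax5 0.098 and Myc 0.12, and with the Div8pos libraries added the slope of Irf4 was 0.20. For lists, unfolded protein response and ER secretion in Div1 against Div0 (0.631) and neutrophil markers in Div8neg against Div0 (0.0224) reversed. Depth limits genes with few counts: 9712 of 21761 were not tested, and where a group had 0 counts large folds are bounds.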

Other observations

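Families named by a pattern of gene symbols were chosen after values were seen, and the tests of patterns below were chosen after their pattern was seen, apart from the rarer against more abundant spike-ins and the slope hypothesis, which were written before their result. Most Toll-like receptor genes were lower in CD138-positive cells. Of 9 tested, 8 were lower and 0 higher in Div8pos than in Div8neg (7 and 1 per cell, camera adjusted p = 6.9e-05, and adjusted p = 0.033 with an estimated correlation), with Tlr9 going from 333.9 to 1.89 CPM, Tlr3 from 49.88 to 0.328, Tlr1 from 96.16 to 3.80 and Tlr7 from 61.37 to 8.86. Tlr2 was lower, at 14.43 and 9.94 CPM, but flipped per cell to a log2 value of 0.037 (adjusted p = 0.900). Tlr4, the LPS receptor, was at 10.78 and 12.16 CPM (adjusted p = 0.308), and it was higher per cell (0.74, adjusted p = 0.00518). Between Div0 and Div8neg 2 of these genes rose, Tlr3 by 1.57 and Tlr12 by 1.36 on the log2 scale, and 3 fell, Tlr1 by 1.44, Tlr4 by 0.84 and Tlr6 by 0.80, all of which flipped per cell (to 0.25, 0.85 and 0.87). Per cell 8 of the 9 were higher and 0 lower in that comparison. Chemokine receptor genes moved apart in Div8pos, with Ccr10 (3.56), Ccr9 (2.91), Cxcr4 (2.47) and Cxcr2 (0.65) higher and Ccr6 (-6.00), Ccr7 (-4.63), Cxcr5 (-2.81) and Cxcr3 (-1.13) among 6 lower of 11 tested. As a family they did not pass (camera adjusted p = 0.210, and adjusted p = 0.280 with an estimated correlation). Nor did 20 integrin genes (5 higher and 9 lower, 6 and 8 per cell, camera adjusted p = 0.160, and adjusted p = 0.260 with an estimated correlation). In Div8neg against Div0 camera gave an adjusted p of 0.800 for the Toll-like receptor, chemokine receptor and integrin families, also with an estimated correlation. Cxcr3 had risen by 3.87 and Cxcr5 fallen by 1.86 from Div0 to Div8neg (for Cxcr5 per cell adjusted p = 0.462).

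Of 37 proteasome subunit genes 35 were higher and 1 lower in Div8neg than in Div0 (median 0.70, camera adjusted p = 4.0e-11, and adjusted p = 0.360 with an estimated correlation), and 32 were higher and 1 lower in Div8pos than in Div8neg (median 0.52; 1.0e-07, and adjusted p = 0.260 with an estimated correlation). Of 20 genes for cytosolic aminoacyl-tRNA synthetases 19 were higher and 0 lower in each of these comparisons (medians 0.76 and 0.74, camera adjusted p = 4.6e-08 and 1.0e-07, and adjusted p = 0.360 and 0.260 with an estimated correlation). Of 74 ribosomal protein genes, many with near copies elsewhere in the genome, 3 were higher and 58 lower in Div8neg than in Div0 relative to all genes (median -0.26), and per cell the family flipped to 74 higher and 0 lower (median 1.42). In Div8pos 68 of the 74 were higher than in Div8neg and 0 lower (median 0.21). Camera gave adjusted p = 3.4e-07 and 1.3e-07 in these comparisons, and adjusted p = 0.750 and 0.360 with an estimated correlation.

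Plasma cell genes were already higher in Div8neg than in Div5, although Div8neg was sorted as CD138-negative. Among the 16 list members higher in both steps, Div8neg showed a median of 8.32% of the excess of Div8pos over Div5 in host 196 and 9.16% in host 197, while Sdc1 showed 0.267 and 0.38%. Leaked CD138-positive cells would give equal shares. The 16 members were chosen as called higher in Div8neg than in Div5, however, which favours high shares, and Sdc1 was not so chosen. The shares therefore do not bear out leakage for these 16 members, but cannot decide on it for the whole list. A further limit is that the gate was on CD138 itself, so cells with less Sdc1 than Div8pos are not excluded. With spike-in scaling, which makes no use of TMM, 23 of the 26 members were higher and 1 lower. Their median was 1.17 (0.998 in host 196 and 1.33 in host 197). So scaled, the median over all genes was 0.49, with 5095 genes higher and 369 lower. A list unchanged relative to all genes would thus have risen too, but the list median lay above 0.49 in both hosts. With DESeq2 size factors, which also make no use of TMM, the list median was 0.655, against -0.01 over all genes. With TMM the list median was 0.665. These values argue against TMM scaling alone as the account of the rise of this list. The biological explanation, a start of the plasma cell programme before CD138 appears, is left as a candidate explanation.

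Total mRNA per cell rose with division. Without the 20 highest genes of the deposited table, which held 6.26 to 8.07% of total mRNA, Div8pos over Div0 was still 4.62-fold in the lower host. A few abundant genes among those counted thus do not account for it. Antibody constant genes were not found in that table, so they are part of neither total. From 20 rarer spike-ins alone the fold was 6.23 in host 196 and 4.61 in host 197, and from 21 more abundant ones 6.02 and 4.39, so unequal spike-in response does not account for it either. Sorted cell numbers or spike-in amounts that differed with the gate could still do so: the hosts differed by up to 1.4-fold within a group, and no value held here separates that from larger cells. Growth in cell size is a candidate biological explanation, and it was not tested.

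Dendritic cell markers were higher in Div1 and Div3 than in Div0. Dendritic cells of 1 kind in the sort would raise Flt3 and Itgax in a fixed ratio, but the ratio of their excess over Div0 went from 45.5 (host 196) and 33.5 (host 197) in Div1 to 18.7 and 15.8 in Div3, 6.99 and 4.24 in Div5 and 1.75 and 0.476 in Div8neg. The lowest value in Div1 was 19.2 times the highest in Div8neg, so 1 fixed ratio was not seen over all these groups. That factor rests on Div8neg, however, whereas the rise to be explained was in Div1 and Div3. The ratios in Div1 and Div3 lay closer together, though without overlap between hosts, so for these groups the test does not decide the explanation. Expression by the B cells is a candidate biological explanation, and it was not tested.

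A hypothesis was that, across genes, the slope over divisions 0 to 5 is related to the signed change between Div8neg and Div8pos. Across 12049 genes the slope over Div0 to Div5 (8 libraries) and the log2 fold change of Div8pos over Div8neg, which share no library, had r = -0.12 and rho = 0.0276. Of 100 shuffles of the division numbers 46 gave an r as far from 0 (range -0.262 to 0.233), so the hypothesis was not borne out. A signed correlation cannot tell whether early-rising genes changed later in both directions.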
